A study of Arabidopsis thaliana with 21 samples.

How the data were processed

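Samples were grouped from the labels into 7 groups of 3 arrays, which the labels describe as biological replicates of separately collected plants. Per the labels, hypocotyls were harvested 24 h after treatment, each replicate over 60 to 80 min, and 4 µg of RNA was labelled per array. Per the submitters' processing notes the deposited values are on a log2 scale and RMA, GCRMA and R 3.2.2 were used. The role of RMA and of GCRMA was not given in the sources used here. The deposited values were used without further scaling, background correction or filtering. Values in the 21 arrays had medians from 6.11 to 6.35, a low peak below 3.5 that held 35.7% to 36.4% of the probe sets of an array, and 0 identical arrays. Correlations between arrays of the same group lay between 0.985 and 0.995, and between arrays of different groups between 0.938 and 0.994.

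Of 22810 probe sets 64 controls were left out and 22746 were tested. The probe table named 1 gene for 13513 probe sets, several for 503 and no gene for 8730, and 13436 of the first were found in the reference by identifier. The 8730 and the 503 were tested and counted, and could not be named or enter a gene list. A gene in a list was represented by the probe set that named it alone and had the highest mean. Depth in the sense of sequencing does not apply, and the number of arrays limits the precision of each value.

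Differences were tested with limma 3.58.1 in R 4.3.3, with a model of group means on all 21 arrays, moderated variances (14 residual and 1.03 prior degrees of freedom) and Benjamini-Hochberg adjustment within each of 11 comparisons at an adjusted p of 0.05. Gene lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, adjusted over 429 tests of 39 lists. Of these 103 passed, 7 with an estimated correlation, 104 with the replicate block and 103 with the mean of the probe sets of a gene. The 7 calls that hold with an estimated correlation are the other auxin response, Aux/IAA and combined auxin response and metabolism lists in IAA against decapitation and IAA against intact, and the list of NRT2.5, GAT1_2.1, QQS, GTR1 and GTR2 in max2 against max1 and max3. The 26 fixed lists hold 360 distinct genes, of which 35 were measured by a probe set naming 1 gene, and were also adjusted over the list alone. Another 35 lists were built from the names of measured genes after the data were opened and before any comparison was computed, and the result of 1 of them and of its members is not reported here, although that list stays in the numbers of tests and calls above. Groups, comparisons, fixed lists, gene naming and the first set of alternatives were chosen before the data were examined.

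Genes were named by rule. For the 6 comparisons of a treatment or mutant with its control, these were the 8 raised and 8 lowered probe sets with the largest change among those with an adjusted p below 0.05, 1 named gene, a symbol other than the locus code and groups that did not overlap. The other comparisons gave 5 each way, and each list gave up to 4 called members, or up to 2 members with the smallest p where none was called. Shared sets gave 8 each way, with no symbol required. Only 1551 of the 22746 probe sets tested named 1 gene with such a symbol, so larger changes can lie among the others.

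Samples with the same replicate number were treated simultaneously per the labels, which makes the numbers a pairing. Residual correlations had a median of 0.361 between arrays of the same number (0.427, 0.127 and 0.401 for numbers 1, 2 and 3) and -0.123 between arrays of different numbers, and the pairing entered as an alternative with the replicate as a block. The first 3 principal components held 54.7%, 12.4% and 7.06% of the variance.

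Alternatives were the replicate block, a fit of only the groups compared, only probe sets naming 1 gene, a change of at least 1 on the log2 scale, a second quantile normalization, subtraction of array medians, leaving out the dimmest probe sets, array quality weights, an intensity trend with robust estimation, leaving out each array in turn, and the camera settings above. Overlaps and correlations that share arrays were compared with 100 simulations of unchanged groups, and groupings with all 10 splits of 6 arrays, 84 splits of 9 or 100 random splits. The simulations drew independent normal noise for each probe set. The test of genes near the mutated loci was first run on all genes called in a mutant against the mean of the other 2 (odds ratios 13.9, 3.08 and 3.34 for max1, max2 and max3). That set held genes changed only in another mutant. It was rerun, after these values were seen, on genes whose own mutant lay further from each of the other 2 than these lay from each other. A bound of 2 SE on the median of the low-oxygen genes within each replicate number was used first and left a shared day open in number 3. It was replaced, after these medians were seen, by camera with the replicate number in the model, because a shared day gives no difference within any number. With 1 array of each number in every group, that model cannot move the median. On simulated data with 50 changed probe sets per size, changes of 0.5, 1, 2 and 4 were recovered in 30%, 72%, 86% and 100% of cases, and 9 of 153 calls were unchanged probe sets. A planted list of 15 genes shifted by 0.7 was found by camera at the preset correlation with an adjusted p of 8.2e-48. Of the other lists of a set of 50, 1 was called. The noise was again independent between probe sets, so this check cannot show how the preset acts on correlated genes. Figures were drawn with matplotlib 3.10.9, numpy 2.4.6 and Python 3.11.15.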

Results

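Transcript levels were measured in hypocotyls, the stem below the seed leaves, of 2-week-old Arabidopsis thaliana plants on 21 ATH1 arrays with 22810 probe sets each. Wild-type plants of the Col-0 strain were left intact, had the shoot tip removed, had it removed and received the auxin indole-3-acetic acid (IAA) at 3 mg per mL, or received NPA, an inhibitor of polar auxin transport, at 3 mg per mL. The max1, max2 and max3 mutants, which branch more than the wild type, were sampled beside them. MAX1 and MAX3 act in the synthesis of strigolactone hormones and MAX2 in the response to strigolactones and karrikins. Lanolin was the carrier in all 7 groups, each group had 3 arrays, and each array held RNA from 120 to 150 hypocotyls collected after 24 h. Array medians lay between 6.11 and 6.35 on the deposited log2 scale, and 29.9% of probe sets stayed below 3.5, where values pile up near background, in every array. The number of arrays limits the precision of each value. Differences below are on the log2 scale, ± stands for the SE of the model with 3 arrays per group, and higher or lower means an adjusted p below 0.05 in limma. The transcripts of MAX1, MAX2 and MAX3 were not analysed here.

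**Figure D1:**
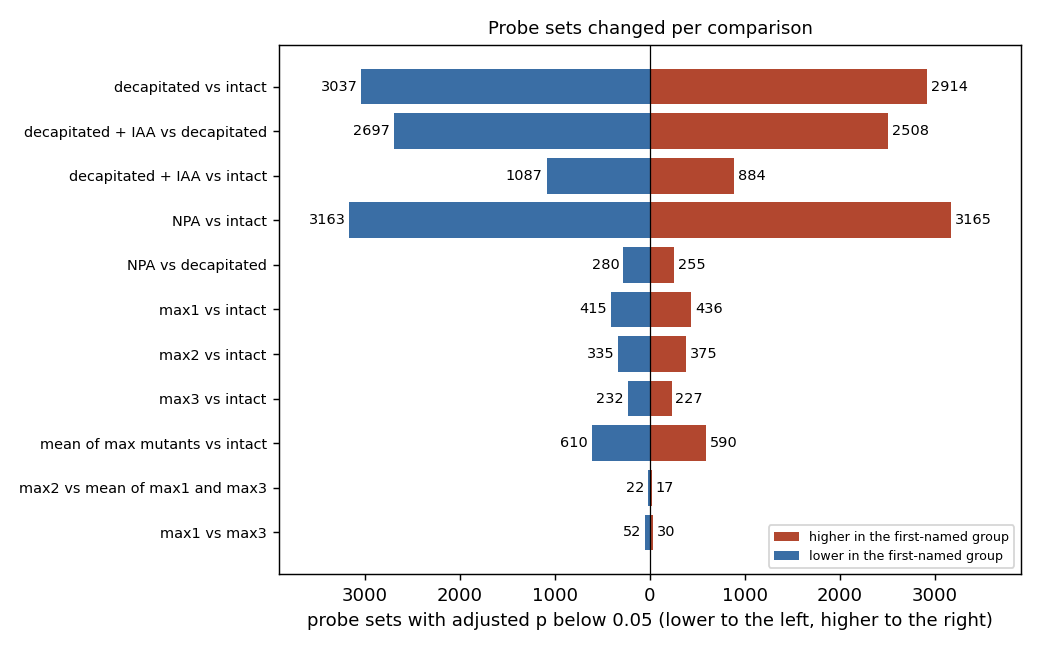
Number of probe sets with an adjusted p below 0.05 (limma, 3 arrays per group) in each comparison, with those lower in the first-named group drawn to the left and those higher to the right. Decapitation (2914 higher, 3037 lower) and NPA (3165 higher, 3163 lower) changed more probe sets than any of the max mutations did.

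Decapitated and intact wild-type hypocotyls were compared to see what changed after the shoot tip, a main source of auxin in the stem, was lost. The endoglucanase genes GH9B8 (AT2G32990) and GH9B13 (AT4G02290) changed by -5.51 ± 0.51 and -4.48 ± 0.25, and the expansin gene EXPA15 (AT2G03090) by -4.20 ± 0.46. TBL34 (AT2G38320), of a family that acetylates wall polysaccharides, fell from 7.35 to 3.07 and IRX15 (AT3G50220), needed for xylan synthesis, fell from 6.49 to 2.56. HAT2 (AT5G47370), an auxin-induced homeodomain transcription factor gene, fell from 9.24 to 4.58 (-4.65 ± 0.35). Subtilase protease genes went both ways, since SBTI1.1 (AT1G01900) fell from 8.04 to 2.67 while SBT3.3 (AT1G32960) rose from 2.95 to 7.78 (4.82 ± 0.35), ATSBT5.2 (AT1G20160) changed by 4.80 ± 0.48 and SBT4.12 (AT5G59090) by 4.03 ± 0.38. Among the other genes with large increases, M17 (AT2G41260) rose from 2.40 to 7.84, the cation transporter gene OCT4 (AT3G20660) from 3.17 to 7.37, the peroxidase gene PRX52 (AT5G05340) changed by 4.42 ± 0.52 and the MYB factor gene MYBC1 (AT2G40970) by 4.22 ± 0.37. SETH6 (AT2G47860) fell from 8.36 to 2.87. The jasmonate-regulated gene JRG21 (AT3G55970) (4.27 ± 0.86) had the highest adjusted p of these 16 genes, 0.00135, and lost its call in a fit of only the 2 groups (adjusted p 0.0664).

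Groups of cell division genes fell after decapitation. Of 24 measured genes of mitosis and cytokinesis, 20 fell and 4 did not pass the test, with a median of -1.93 (camera adjusted p = 4.3e-16, and adjusted p = 0.181 with an estimated correlation). Among them the kinesin gene AT1G72250 changed by -4.00 ± 0.37 and the Aurora kinase gene AUR2 (AT2G25880) by -3.16 ± 0.28. 5 of 6 histone H2B genes fell, with HTB2 (AT5G22880) at -1.29 ± 0.34 (adjusted p = 0.354 with an estimated correlation). Of 9 tubulin and actin genes 7 fell and 1 rose, with a median of -1.51 and TUB5 (AT1G20010) at -2.78 ± 0.39 (adjusted p = 0.143 with an estimated correlation). PRL (AT4G02060), a subunit of the DNA replication helicase, changed by -1.95 ± 0.26.

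In the trichome birefringence-like (TBL) family 9 of 22 members fell, among them TBL45 (AT2G30010) (-3.20 ± 0.20) and TBL38 (AT1G29050) (-2.66 ± 0.19), and none rose, although 5 rose once array medians were subtracted (adjusted p = 0.172 with an estimated correlation). In the lignin and xylan list 5 of 11 genes fell, including IRX15-L (AT5G67210) (-3.80 ± 0.36) and the xylan synthase gene GUT2 (AT1G27440) (-2.66 ± 0.22) (adjusted p = 0.284 with an estimated correlation). The cambium receptor kinase gene MOL1 (AT5G51350) changed by -1.14 ± 0.19, the phloem gene OPS (AT3G09070) by -1.33 ± 0.28 and the expansin gene EXPA4 (AT2G39700) by -2.72 ± 0.17. 6 of 18 CLE and RALF peptide genes fell, among them CLE44 (AT4G13195) (-2.37 ± 0.21), which encodes a peptide that keeps vascular stem cells undifferentiated, and the list had a median of -0.04 that became 0.08 with array medians subtracted (adjusted p = 0.354 with an estimated correlation). The auxin-response repressor genes IAA30 (AT3G62100) and IAA18 (AT1G51950) changed by -3.51 ± 0.23 and -1.69 ± 0.38, and WES1 (AT4G27260), an enzyme that couples auxin to amino acids, by -3.27 ± 0.55. The type-A cytokinin response regulators split, with ARR15 (AT1G74890) at -3.69 ± 0.32 and RR16 (AT2G40670) rising from 2.70 to 6.30. Gibberellin receptor genes GID1B (AT3G63010) and GID1A (AT3G05120) rose by 2.51 and 1.51. DFR (AT5G42800), an enzyme of anthocyanin synthesis, changed by -3.46 ± 0.79.

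Of 20 plastid-encoded genes of the plastid's own transcription and translation 17 rose, with a median of 1.11 (camera adjusted p = 8.2e-08, and adjusted p = 0.354 with an estimated correlation), among them the ribosomal protein gene rps16 (1.42 ± 0.30) and the RNA polymerase gene rpoC1 (1.41 ± 0.24). 16 of 43 plastid-encoded photosynthesis genes rose, including ndhE (1.35 ± 0.32), a subunit of the NDH complex (adjusted p = 0.616 with an estimated correlation). Of 19 nuclear genes of photosynthesis 9 rose, with NdhN (AT5G58260) at 2.25 ± 0.40 (adjusted p = 0.581 with an estimated correlation). Only 2 of 14 leaf, 1 of 10 shoot apex and 1 of 11 root markers were measured, too few to judge the tissue make-up. The leaf markers LHCB4.2 and RCA stood at -0.12 ± 0.26 and 0.94 ± 0.42. The shoot apex marker CLV3 stood at 0.01 ± 0.02 and the root marker EXPA7 at 0.02 ± 0.02. None of these passed the test. Nor did the abscisic acid genes COR15A (1.53 ± 0.69) and LEA4-5 (-0.09 ± 0.29), the clock gene GI (0.88 ± 0.67) or the wound-response gene STZ (0.43 ± 0.53).

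In all, decapitation raised 2914 and lowered 3037 of 22746 probe sets (26.2%), of which 1314 and 1668 moved by at least 1 on the log2 scale. Adjusted over the list alone, the fixed lists gave the same counts as over all genes, except that all 3 measured gibberellin genes were then higher. Subtracting array medians shifted the median difference of all probe sets by 0.11 and turned the split to 8909 higher and 2781 lower. The mitosis, histone H2B, tubulin and plastid lists kept the sign of their medians under that scaling and under a second quantile normalization.

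**Figure D2:**
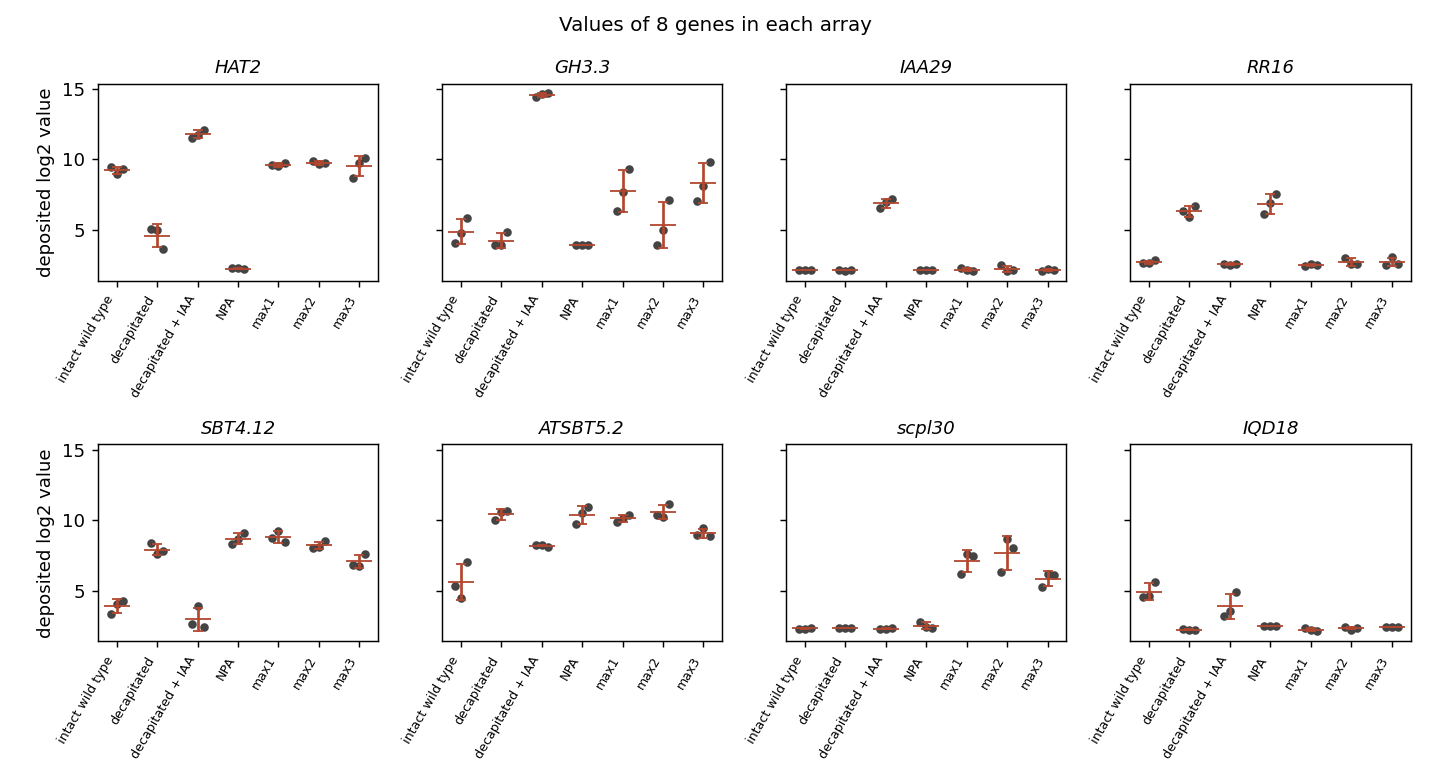
Deposited log2 values of 8 genes in each of the 21 arrays (points), with the group mean (long line) and SD (bars, 3 arrays per group). HAT2 fell from 9.24 to 4.58 after decapitation and stood at 11.79 with IAA, and scpl30 stood near background in every wild-type group and above 5 in every max mutant array.

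Decapitated hypocotyls with and without IAA were compared to see which changes auxin given to the stump produced. GH3.3 (AT2G23170), a gene for an enzyme that couples IAA to amino acids, rose from 4.23 to 14.61 (10.38 ± 0.85), and WES1 of the same family changed by 6.87 ± 0.55. HAT2 rose from 4.58 to 11.79, IAA30 from 3.15 to 8.94, IAA29 (AT4G32280) from 2.12 to 6.89 and LBD16 (AT2G42430), a transcription factor gene of lateral root formation, from 2.02 to 7.79. SETH6 and SBTI1.1 rose from 2.87 to 8.88 and from 2.67 to 7.51. Genes that had risen after decapitation fell, with M17 going from 7.84 to 2.34, SBT4.12 from 7.92 to 2.95 and RR16 from 6.30 to 2.55. GTR2 (AT5G62680), a glucosinolate transporter gene, changed by -4.09 ± 0.21, the sugar transporter gene SFP2 (AT5G27360) by -3.56 ± 0.34, scpl31 (AT1G11080) by -3.19 ± 0.44, OCT4 by -3.34 ± 0.30 and MYBC1 by -3.30 ± 0.37. The highest adjusted p among these 16 genes was 5.8e-05.

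All 7 measured genes of the list of other auxin response genes rose with IAA, with a median of 5.77 (adjusted p = 0.0023 with an estimated correlation), and 2 of 4 Aux/IAA genes rose (adjusted p = 0.0419 with an estimated correlation). WAG2, a kinase gene that directs auxin transport, changed by 4.58 ± 0.38. Cell division genes rose, with 21 of 24 mitosis genes higher and a median of 1.57 (adjusted p = 0.181 with an estimated correlation), AT1G72250 at 3.09 ± 0.37, AUR2 at 2.52 ± 0.28 and PRL at 1.96 ± 0.26. Of 9 tubulin and actin genes 6 rose and 1 fell (adjusted p = 0.181 with an estimated correlation), TUB5 by 2.32. GH9B8 changed by 4.14 ± 0.51, EXPA15 by 3.94 ± 0.46 and TBL34 by 3.96 ± 0.31. The xyloglucan enzyme gene XTH20 (AT5G48070), at 2.79 in intact and 2.88 in decapitated plants, stood at 6.81 with IAA. 14 of 43 cytosolic ribosomal protein genes rose, with a median of 0.20 (adjusted p = 0.375 with an estimated correlation). Gibberellin receptor genes fell, with GID1B at -3.08 ± 0.53, GID1A at -1.98 ± 0.17 and GID1C at -1.18 ± 0.30 (camera adjusted p = 0.0137, and adjusted p = 0.181 with an estimated correlation). Of 20 plastid gene expression genes 12 fell, with a median of -0.78 (adjusted p = 0.581 with an estimated correlation), and 11 of 19 nuclear photosynthesis genes fell, NdhN at -2.30 ± 0.40 (adjusted p = 0.582 with an estimated correlation). ARR15 changed by 2.75 ± 0.32.

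IAA raised 2508 and lowered 2697 probe sets against decapitation alone, a split that became 2191 and 4836 with array medians subtracted. Adjusted over the list alone, the fixed lists gave the same counts, apart from 2 in place of 1 of 4 expansin and xyloglucan enzyme genes, a list whose call was lost with the replicate block (adjusted p 0.0651), without decapitated replicate 3 (0.0956) and without IAA replicate 1 (0.0506), and ranged from 0.0167 to 0.354 over its alternatives. The highest of these is its adjusted p = 0.354 with an estimated correlation.

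Of the 5951 probe sets changed by decapitation, 3702 (62.2%) changed back with IAA. AT1G12080 fell by 7.60 and rose by 7.71, AT1G54020 fell by 6.96 and rose by 7.83, and AT5G50915 rose from 1.80 to 8.72 and returned to 1.80. Of the 3702, 1846 had risen and 1856 had fallen after decapitation, or 3838 and 1679 with array medians subtracted. By the test 3172 were not called against intact, 401 were still changed in the direction of decapitation and 129 had passed the intact level. Lack of a call with 3 arrays per group does not show a return to the intact level. The replicate block raised the number called between IAA and intact, and this split was not recomputed with it. A further 53 moved the same way with IAA as with decapitation. Independent lists would share 346 and 335. At an unadjusted p below 0.05, 5186 changed and changed back, against a mean of 243 and at most 277 in simulated unchanged groups measured against the same decapitated arrays. With 3 decapitated arrays in common, which cannot be divided into 2 sets of 2, part of the excess may come from the shared controls.

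Decapitated plants with IAA and intact plants were compared to see which transcripts differed after auxin replaced the shoot tip. GH3.3 was higher by 9.74 ± 0.85, LBD16 rose from 1.99 to 7.79, IAA29 changed by 4.78 ± 0.12, XTH20 rose from 2.79 to 6.81 and the pectin methylesterase gene ATPMEPCRD (AT2G43050) from 2.51 to 7.12. Lower were DFR (-5.02 ± 0.79), the bHLH factor gene ALC (AT5G67110) (-2.78 ± 0.39), GTR2 (-2.19 ± 0.21) and CYP78A9 (AT3G61880) (-2.88 ± 0.48), which lost its call in a fit of only these groups (adjusted p 0.0633). ORA47 (AT1G74930), a jasmonate factor gene, stood at -2.72 ± 0.80 with an adjusted p of 0.0475 and lost its call when any 1 of the 6 arrays was left out (0.0537 without IAA replicate 3 to 0.153 without intact replicate 3). 6 of 7 other auxin response genes were higher, and 7 adjusted over the list alone, with a median of 3.58 (adjusted p = 0.00052 with an estimated correlation), and 2 of 4 Aux/IAA genes were higher (adjusted p = 0.0419 with an estimated correlation), with 1 lower adjusted over the list alone. WAG2 was higher by 3.51. Of 43 cytosolic ribosomal protein genes 10 were higher, with a median of 0.23 (adjusted p = 0.207 with an estimated correlation), and of 12 class III peroxidase genes 4 were higher and 1 lower, with PRX52 at 3.37 ± 0.52 (adjusted p = 0.288 with an estimated correlation). Among the mitosis genes 1 of 24 was lower, AT3G02640 (-1.03 ± 0.29), a call lost without any intact replicate or IAA replicates 2 and 3 (adjusted p up to 0.159). In all 884 probe sets were higher and 1087 lower, or 995 and 945 with array medians subtracted. The total of 1971 was 2962 with the replicate block, 1284 without IAA replicate 2 and 1230 without IAA replicate 3.

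NPA and intact hypocotyls were compared to see what blocking auxin transport changed in plants that kept the shoot tip. HAT2 fell from 9.24 to 2.23 (-7.01 ± 0.35), SBTI1.1 from 8.04 to 2.27, SETH6 from 8.36 to 3.37 and TBL34 changed by -4.15 ± 0.31. The thaumatin-like gene ATLP-1 (AT1G18250) changed by -5.04 ± 0.18, the xyloglucan enzyme gene XTH16 (AT3G23730) by -4.18 ± 0.49, and the anthocyanin genes DFR and UF3GT (AT5G54060) by -5.32 ± 0.79 and -4.07 ± 0.99. RR16 rose from 2.70 to 6.85. M17 rose from 2.40 to 7.26 and OCT4 from 3.17 to 7.17, both from values near background. SBT4.12 changed by 4.80 ± 0.38, ATSBT5.2 by 4.77 ± 0.48, MYBC1 by 4.19 ± 0.37, JRG21 by 4.11 ± 0.86 and the calmodulin-like gene CML38 (AT1G76650) by 3.89 ± 0.64. The highest adjusted p among these 16 genes was 0.00569.

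Of 24 mitosis genes 20 fell, with a median of -2.26 (camera adjusted p = 4.1e-19, and adjusted p = 0.161 with an estimated correlation), the Aurora kinase genes AUR1 (AT4G32830) and AUR2 at -3.70 ± 0.35 and -3.45 ± 0.28. 5 of 6 histone H2B genes fell (adjusted p = 0.345 with an estimated correlation), and 7 of 9 tubulin and actin genes fell and 1 rose, with TUB5 at -2.49 ± 0.39 (adjusted p = 0.161 with an estimated correlation). PRL changed by -2.64 ± 0.26, MOL1 by -1.41 ± 0.19, GUT2 by -2.46 ± 0.22, OPS by -1.84 ± 0.28, EXPA4 by -3.78 ± 0.17 and ARR15 by -2.29 ± 0.32. Of 22 TBL genes 10 fell, or 8 with 5 higher once array medians were subtracted, and TBL45 stood at -3.40 ± 0.20 (adjusted p = 0.243 with an estimated correlation). GID1B and GID1A rose by 2.35 and 1.52. Of 20 plastid gene expression genes 16 rose, with a median of 0.93 and rpoC1 at 1.08 ± 0.24 (adjusted p = 0.564 with an estimated correlation). 9 of 43 cytosolic ribosomal protein genes fell and 1 rose with a median of -0.08, which became 0.05 with 8 higher and 3 lower once array medians were subtracted (adjusted p = 0.70 with an estimated correlation, and a preset call lost without intact replicate 2, at 0.169, or NPA replicate 2, at 0.0713). IAA30 changed by -3.76 ± 0.23 and WES1 by -2.29 ± 0.55, and adjusted over the list alone 2 of 4 Aux/IAA genes were lower in place of 1.

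NPA raised 3165 and lowered 3163 probe sets. Subtracting array medians shifted the median difference by 0.13 and turned the split to 10056 higher and 2849 lower.

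**Figure D3:**
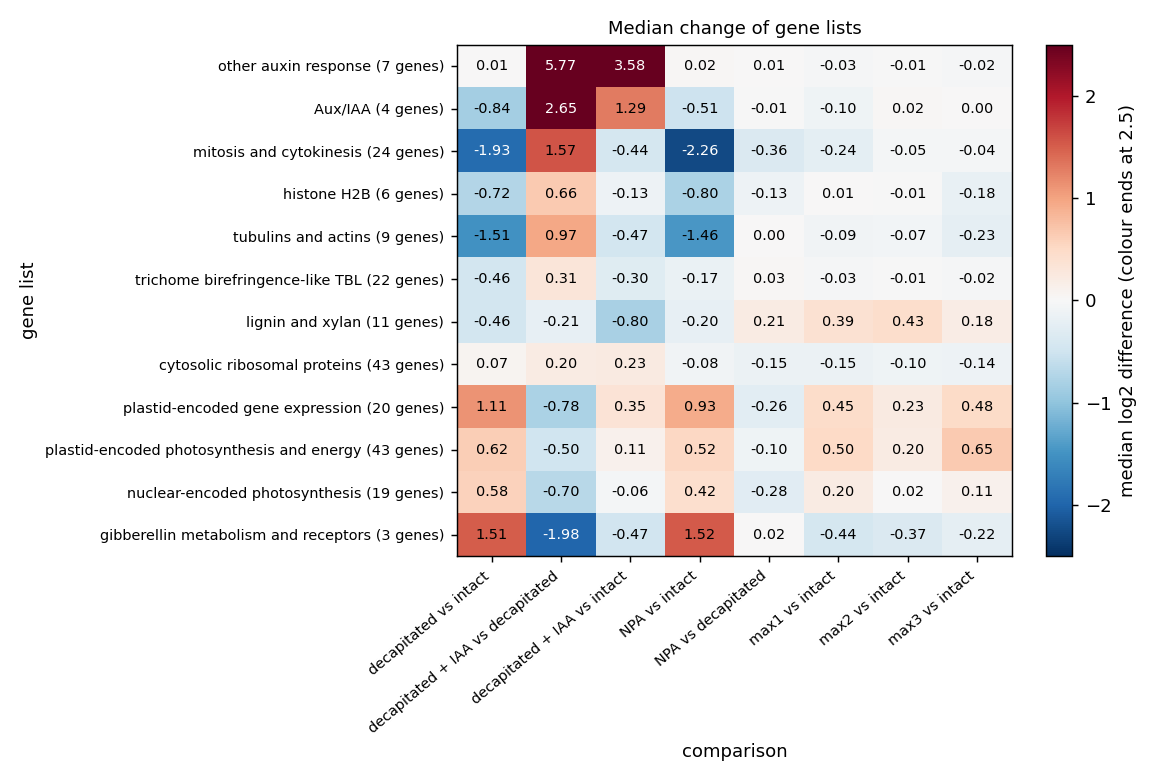
Median log2 difference of 12 gene lists (vertical axis, measured genes in brackets) in 8 comparisons (horizontal axis), with colour from blue (lower in the first-named group) to red (higher) ending at 2.5. Mitosis genes stood at -1.93 after decapitation, -2.26 under NPA and 1.57 when IAA was added to decapitated plants.

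The overlap of decapitation and NPA was computed to see whether both treatments moved the same transcripts. AT3G11930 rose from 2.58 in intact plants, near background, to 10.64 and 11.77, and AT2G15780 from 1.99 to 10.58 and 10.59. AT1G54020 fell from 9.76 to 2.80 and 2.75, and AT1G12080 from 12.02 to 4.43 and 5.14. Together 4532 probe sets changed the same way, 2013 higher and 2519 lower (7716 and 2278 with array medians subtracted). That is 76.2% of those changed by decapitation, and 7 changed in opposite directions. Independent lists would share 405 and 422. At an unadjusted p below 0.05, 5934 changed the same way, against a mean of 242 and at most 288 in simulated unchanged groups measured against the same intact arrays. Across genes, which are not independent replicates, the log2 differences had a Pearson r of 0.916 and a Spearman rho of 0.840, with a covariance of 0.770 against 0.0286 from the shared intact arrays alone. The 3 intact arrays cannot be divided into 2 sets of 2, so part of the excess may come from the shared controls.

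NPA and decapitation were compared directly to see where they differed. AtLEA4-1 (AT1G32560), a late embryogenesis abundant gene of the dehydration response, was higher under NPA by 2.77 ± 0.24, the endoglucanase gene GH9B18 (AT4G39010) went from 3.16 to 4.72 and the lignin enzyme gene CCOAMT (AT1G67980) from 3.11 to 4.64. PRX52 was lower under NPA, at -5.41 ± 0.52 (8.24 to 2.83), as were HAT2 (4.58 to 2.23), SFP2 (-1.87 ± 0.34) and EXPA4 (-1.05 ± 0.17). Cytosolic ribosomal protein genes had a median of -0.15 with 1 of 43 lower (camera adjusted p = 5.1e-07, and adjusted p = 0.355 with an estimated correlation), and mitosis genes a median of -0.36 with 1 of 24 lower (camera adjusted p = 6.1e-05, and adjusted p = 0.494 with an estimated correlation). In total 255 probe sets were higher and 280 lower, 262 and 234 with array medians subtracted, and 134 and 93 when at least 1 on the log2 scale was asked for. The total of 535 was 1068 with the replicate block, 270 without decapitated replicate 2, and 0 in a limma fit of only the 2 groups, where 2557 had an unadjusted p below 0.05 and each gene named here lost its call (adjusted p 0.0860 to 0.221).

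**Figure D4:**
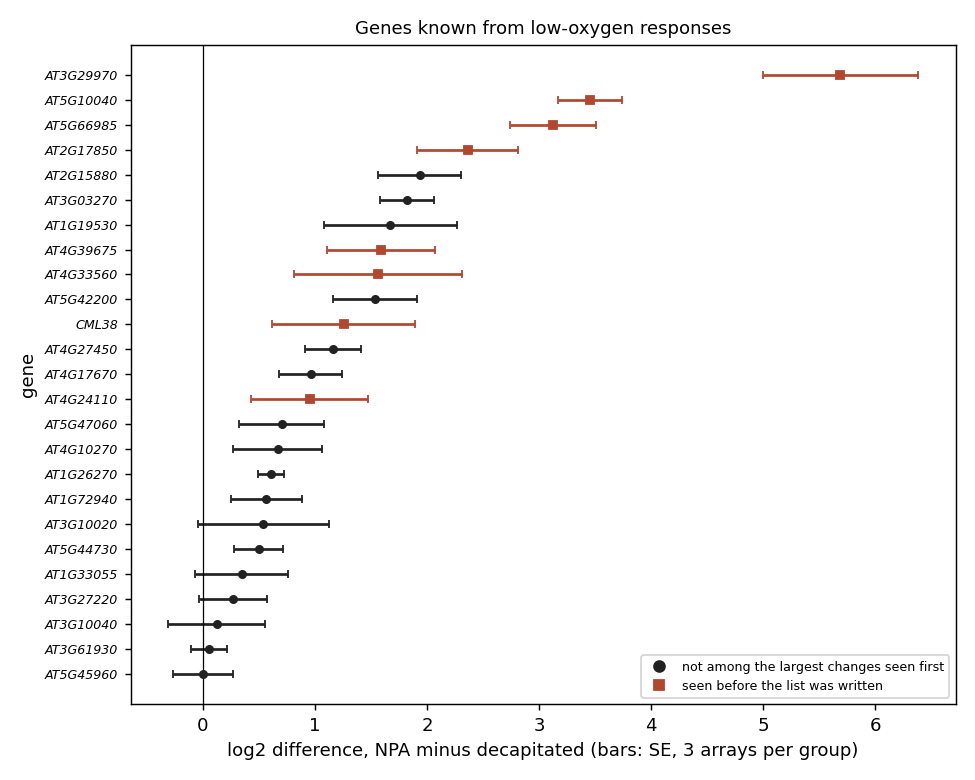
NPA minus decapitated log2 difference with SE (bars, 3 arrays per group) of 25 genes known from low-oxygen responses, with red squares for genes seen before the list was written and black circles for the others. The horizontal axis is the log2 difference and each gene is 1 line.

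The max1 mutant and intact wild type were compared to see what differed in the mutant. APA1 and AT1G11280, named here, lie in a group of max1 genes on chromosome 1 for which a strain variant was not tested. The lowest value of this comparison was that of AT2G25450, near the MAX1 locus, at 3.75 in max1 and 12.47 in intact (-8.72). AT1G11280 stood at 2.42 in max1 and 8.44 in intact (-6.02). In max2 and max3 AT2G25450 stood at 12.89 and 13.20 and AT1G11280 at 8.60 and 8.66. scpl30 (AT4G15100), a serine carboxypeptidase-like gene, rose from 2.30 to 7.08 (4.78 ± 0.46), SBT4.12 changed by 4.93 ± 0.38, ATSBT5.2 by 4.52 ± 0.48, and QQS (AT3G30720), a gene of carbon and nitrogen allocation, rose from 2.44 to 5.62. ATPMEPCRD rose from 2.51 to 5.34 and the expansin gene EXPA9 (AT5G02260) changed by 2.57 ± 0.50. IQD18 (AT1G01110), of a calmodulin-binding family, fell from 4.92 to 2.23, the aspartic protease gene APA1 (AT1G11910) changed by -2.13 ± 0.12, the methionine lyase gene MGL (AT1G64660) by -2.08 ± 0.32, and TRM22 (AT1G67040) and TRM28 (AT5G03670), of a family tied to microtubule arrays, by -1.98 ± 0.21 and -1.75 ± 0.31. TBL38 (AT1G29050), RALFL34 (AT5G67070) and GH9B18 stood at 1.45 ± 0.19, -0.90 ± 0.11 and -1.32 ± 0.17, and the vascular peptide gene CLE41 (AT3G24770) at -0.96 ± 0.18. Calls of BCAT4 (4.92 ± 1.25, adjusted p 0.149 without max1 replicate 3), CML38 (2.89 ± 0.64, adjusted p 0.0843 without intact replicate 3), CHR34 (-2.30 ± 0.59, adjusted p 0.137 without max1 replicate 1), TUB5 (-1.89 ± 0.39, adjusted p 0.0603 without intact replicate 3), ALC (-1.87 ± 0.39, adjusted p 0.0619 without intact replicate 3), WAG2 (1.73 ± 0.38, adjusted p 0.0785 without max1 replicate 3), ARR15 (-1.21 ± 0.32, adjusted p 0.171 without max1 replicate 2) and GUT2 (1.10 ± 0.22, adjusted p 0.0557 without max1 replicate 3) were lost when single arrays were left out, shown by the fit with the highest adjusted p. Plastid-encoded photosynthesis genes had a median of 0.50 with 1 of 43 higher (camera adjusted p = 4.3e-16, and adjusted p = 0.323 with an estimated correlation), and 2 of 9 subtilase genes rose (adjusted p = 0.181 with an estimated correlation). In all 436 probe sets were higher and 415 lower, or 405 and 589 with array medians subtracted. The total of 851 was 1418 with the replicate block, 198 in a fit of only these groups, which ended the calls of ATSBT5.2, EXPA9, MGL, TRM22 and CLE41 (adjusted p 0.0538 to 0.160), and 499 without max1 replicate 3.

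The max2 mutant and intact wild type were compared in the same way. scpl30 rose from 2.30 to 7.68 (5.37 ± 0.46), ATSBT5.2 changed by 4.97 ± 0.48, SBT4.12 by 4.32 ± 0.38, the folate synthesis gene FOLB1 (AT3G11750) by 2.28 ± 0.25, TBL34 by 1.61 ± 0.31 and TBL38 by 1.47 ± 0.19. IQD18 fell from 4.92 to 2.33, TRM28 changed by -2.45 ± 0.31, ALC by -2.31 ± 0.39, PTL (AT5G03680), a trihelix factor gene of floral organs, by -1.81 ± 0.31, and TRM22 by -1.77 ± 0.21. GUT2 was higher by 1.26 ± 0.22, and CLE41, RALFL34 and the sugar transporter gene TMT1 (AT1G20840) stood at -1.01 ± 0.18, -0.82 ± 0.11 and -1.47 ± 0.27. Calls of ATPMEPCRD (1.64 ± 0.41, adjusted p 0.137 without max2 replicate 3), the ureide enzyme gene AAH (1.62 ± 0.38, adjusted p 0.111 without max2 replicate 1), GAT1_2.1 (-4.44 ± 1.13, adjusted p 0.181 without max2 replicate 2), WES1 (-2.18 ± 0.55, adjusted p 0.172 without max2 replicate 3), TUB5 (-1.89 ± 0.39, adjusted p 0.0632 without intact replicate 3) and ARR15 (-1.50 ± 0.32, adjusted p 0.0716 without max2 replicate 3) were lost when single arrays were left out, for ATPMEPCRD with any 1 of the 6. Of 11 lignin and xylan genes 2 were higher, with a median of 0.43 (camera adjusted p = 0.00191, and adjusted p = 0.224 with an estimated correlation). In all 375 probe sets were higher and 335 lower, or 359 and 445 with array medians subtracted. The total of 710 was 1169 with the replicate block, 450 without intact replicate 2, 469 without max2 replicate 2, and 106 in a fit of only these groups, which ended the calls of scpl30, ATSBT5.2, TBL34, IQD18, ALC, GUT2 and CLE41 (adjusted p 0.0573 to 0.200).

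The max3 mutant and intact wild type were compared in the same way. The lowest value of this comparison was that of AT3G07230, at 2.22 in max3 and 11.16 in intact (-8.94). In max1 and max2 this gene stood at 11.57 and 11.59. ATPMEPCRD rose from 2.51 to 6.71, scpl30 from 2.30 to 5.85 (3.55 ± 0.46), WAG2 from 3.36 to 6.25, ATSBT5.2 changed by 3.45 ± 0.48, SBT4.12 by 3.18 ± 0.38 and FOLB1 by 1.54 ± 0.25. IQD18 fell from 4.92 to 2.43, TRM22 changed by -2.09 ± 0.21, TRM28 by -1.68 ± 0.31, MGL by -1.81 ± 0.32, ARR15 by -1.80 ± 0.32, and the stress factor gene TINY2 (AT5G11590) fell from 3.65 to 2.24. GH9B18 and RALFL34 stood at -1.05 ± 0.17 and -0.82 ± 0.11, and the dehydrin gene COR47 (AT1G20440) at 1.23 ± 0.22. Calls of GH3.3 (3.45 ± 0.85, adjusted p 0.171 without max3 replicate 3), MYR2 (1.44 ± 0.35, adjusted p 0.163 without max3 replicate 1), ALC (-1.88 ± 0.39, adjusted p 0.103 without max3 replicate 1) and ULT1 (-1.16 ± 0.28, adjusted p 0.162 without max3 replicate 2) were lost when single arrays were left out, for ULT1 with any 1 of the 6. Of 43 plastid-encoded photosynthesis genes 5 were higher, with a median of 0.65 (camera adjusted p = 1.4e-26, and adjusted p = 0.202 with an estimated correlation). In all 227 probe sets were higher and 232 lower, or 210 and 326 with array medians subtracted. The total of 459 was 971 with the replicate block, 123 in a fit of only these groups, which ended the calls of ATSBT5.2, FOLB1, IQD18, MGL, ARR15, RALFL34 and COR47 (adjusted p 0.0543 to 0.136), 283, 234 and 304 without intact replicates 1, 2 and 3, and 217 and 272 without max3 replicates 1 and 2.

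The 3 mutants together were set against intact wild type to see what the max mutations had in common. Among genes with a symbol, scpl30 (4.57 ± 0.37), ATSBT5.2 (4.31 ± 0.39), SBT4.12 (4.14 ± 0.31) and ATPMEPCRD (2.89 ± 0.33) had some of the largest increases in the mean of the mutants. IQD18 (-2.60 ± 0.26), ALC (-2.02 ± 0.31), TRM28 (-1.96 ± 0.25) and TRM22 (-1.94 ± 0.18) had the largest decreases among them. Over all probe sets the lowest value was -4.39. AT1G30760 rose by 5.74, 6.20 and 3.91 in max1, max2 and max3, and AT2G20670 changed by -2.92, -3.19 and -1.98. ARR15 changed by -1.50 ± 0.26, GUT2 by 1.11 ± 0.18, TBL34 by 1.49 ± 0.26 and TBL38 by 1.28 ± 0.16. BCAT4 (AT3G19710) (4.34 ± 1.02), of methionine-derived glucosinolate synthesis, lost its call without any 1 of intact replicates 1, 2 and 3 (adjusted p up to 0.0908, without replicate 3), and BGLU47 (AT4G21760) (-1.89 ± 0.49) in 7 such fits (up to 0.136, without intact replicate 1). The mean differed from intact in 590 higher and 610 lower probe sets, or 541 and 897 with array medians subtracted, and the total of 1200 was 2010 with the replicate block and 764, 719 and 769 without intact replicates 1, 2 and 3. In all 3 mutants 114 probe sets were higher and 121 lower, 235 in total, against 0.0717 and 0.0623 for independent lists. At an unadjusted p below 0.05, 1302 changed the same way in all 3, against a mean of 95.7 and at most 128 in simulated unchanged groups measured against the same intact arrays. The 3 intact arrays cannot be divided into 2 sets of 2, so part of the excess may come from the shared controls. The total of 235 was 423 with the replicate block, 17 in fits of only the groups compared, 141 without intact replicate 2, and 144 and 136 without max3 replicates 1 and 2.

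The mean of the mutants was also set against decapitation, since both remove a brake on branching. IQD18, ALC and TRM28 fell in both, with decapitation at -2.71 ± 0.32, -3.11 ± 0.39 and -1.07 ± 0.31. Of the 7 groups, intact had the highest mean of each gene (4.92, 6.30 and 6.77). With IAA they stood at 3.88, 3.53 and 5.98. High values in the shared intact arrays would give this pattern too, which was not tested. SBT4.12 and ATSBT5.2 rose in both. In contrast, scpl30 stood at 0.02 ± 0.46 after decapitation, and TBL34 and GUT2 fell after decapitation and rose in the mutants. Both were higher for 167 probe sets and both lower for 328, against 75.6 and 81.4 for independent lists, while 157 were higher in the mutants and lower after decapitation (78.8) and 69 the reverse (78.1). The shared intact arrays alone push both comparisons the same way. These counts were not simulated, so the share due to those arrays is not known. Across genes, which are not independent replicates, r was 0.129 and rho 0.184, where unchanged groups measured against the same intact arrays gave an r of 0.610. The covariance was 0.0478 against 0.0285 from the shared arrays, a difference of 0.0193. Without intact replicates 1 and 2 in turn r was 0.155 and 0.176, without decapitated replicate 1 it was 0.110 and without max2 replicate 3 it was 0.102.

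The mutants were compared with each other because MAX2 acts in hormone response and MAX1 and MAX3 in hormone synthesis. Against the mean of max1 and max3, max2 had lower ATPMEPCRD (-1.87 ± 0.35), with means of 5.34, 4.15 and 6.71 in max1, max2 and max3. QQS also differed (-1.58 ± 0.13), but through max1 (5.62), since max2 (2.42) stood near max3 (2.38) and intact (2.44). The beta-glucosidase gene BGLU41 (AT5G54570) differed (0.59 ± 0.11) because max3 (2.89) stood near intact (2.86) while max1 and max2 were at 3.65 and 3.86. The call of ATPMEPCRD (adjusted p 0.0488) was lost with the replicate block (0.0661) and reached 0.303 in a fit of only the mutants. An added list of NRT2.5, GAT1_2.1, QQS, GTR1 and GTR2, which share no single function, had a median of -0.47 with only QQS called (camera adjusted p = 9.2e-06, and adjusted p = 0.0419 with an estimated correlation), and plastid-encoded photosynthesis genes had a median of -0.38 (camera adjusted p = 8.5e-21, and adjusted p = 0.256 with an estimated correlation). In total 17 probe sets were higher and 22 lower, or 20 and 16 after a second quantile normalization and 20 and 19 with array medians subtracted, and the total of 39 was 5 in a fit of only the mutants, 25 without max2 replicate 2 or without max3 replicate 1, and 74 without max2 replicate 3. Between max1 and max3, QQS rose from 2.38 to 5.62 (3.24 ± 0.15), the cyclophilin gene SQN (AT2G15790) from 2.35 to 4.46 and ATCOAE (AT2G27490) changed by 1.52 ± 0.19, while APA1 (-2.26 ± 0.12) and PIP (AT2G14260) (-1.52 ± 0.22) were lower in max1. The starch enzyme gene APL4 (AT2G21590) (2.07 ± 0.36), BGLU41 (0.75 ± 0.12) and the leucine breakdown gene MCCA (AT1G03090) (-1.18 ± 0.20) lost their calls when single arrays were left out, APL4 at 0.0841 without max3 replicate 1, BGLU41 at 0.0600 without max1 replicate 1 and MCCA at 0.0728 without max3 replicate 3. In all 30 probe sets were higher and 52 lower in max1, and the total of 82 was 144 with the replicate block and 17 in a fit of only these groups, which ended the calls of SQN, ATCOAE and PIP (adjusted p 0.0556 to 0.245).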

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

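The tests of the low-oxygen list by replicate number and with that number in the model and of genes near the mutated loci were chosen only after the results were seen, and the low-oxygen list and the rule for genes changed in a mutant itself were written after the largest changes had been seen. NPA and decapitation, max2 and the other max mutants, and max1 and max3 stand out here because the groups differed in a direct test of the difference.

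Between NPA and decapitation 535 probe sets differed. AtLEA4-1 (2.77), GH9B18 (1.56), CCOAMT (1.53) and the iron-sulphur cofactor gene SUFE2 (2.07) and expansin-like gene EXLA3 (1.56) were higher under NPA. PRX52 (-5.41), HAT2 (-2.35), SFP2 (-1.87), the glutathione transferase gene GSTU20 (-1.89) and NdhN (-1.76) were lower. SUFE2 lost its call without any 1 of the 6 arrays (adjusted p 0.0506 to 0.148), and EXLA3, GSTU20 and NdhN lost theirs without NPA replicate 1 (0.111, 0.164 and 0.105), among others. The 10 splits of the 6 arrays are too few to reach a share below 0.05. The real split called 0 probe sets in a limma fit of the 2 groups without the pairing, with 2557 at an unadjusted p below 0.05, and the highest other called 1. With a real count of 0 all 10 of 10 splits give as many by construction, and the replicate block gave 1068.

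Between max2 and the mean of max1 and max3 39 probe sets differed, with ATPMEPCRD at -1.87, a call (adjusted p 0.0488) lost with the replicate block (0.0661) and in a fit of only the mutants (0.303). Of 24 nuclear genes named among them, 7 were changed in max2 itself. 1 of these, AT5G63180, stood near background at 3.15 in max2 and 2.96 in intact, and at 6.43 and 6.54 in max1 and max3 (limma adjusted p 0.00043). Another, AT2G19970, stood at 9.75 in max2, 10.95 and 10.93 in max1 and max3, and 11.74 in intact (limma adjusted p 4.3e-05). ATPMEPCRD also differed between max3 and the mean of max1 and max2 (1.96, limma adjusted p 0.0275). In fits of 2 groups, which put the difference of max1 and max3 into the noise, the splits do not exclude chance. The real split called 0 probe sets in limma, with 807 at an unadjusted p below 0.05, so that 84 of 84 splits give as many by construction. The highest other, with replicate 1 of all 3 mutants against the rest, called 63 and follows a shared day. With the replicate block the comparison called 50. Between max1 and max3 82 probe sets differed, with QQS (3.24), SQN (2.11), APL4 (2.07), ATCOAE (1.52) and BGLU41 (0.75) higher in max1 and APA1 (-2.26), PIP (-1.52) and MCCA (-1.18) lower. SQN, APL4, ATCOAE and PIP lie between AT2G14110 and AT2G27490, and APA1 between AT1G03660 and AT1G12230. For these stretches, taken up below, a strain variant stays open. The 10 splits are too few to reach a share below 0.05, with 17 probe sets in the real split and 1 in the highest other.

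Among the genes that differed most between NPA and decapitation were several known from low-oxygen responses, such as AT3G29970 (5.69 ± 0.69, from 3.49 to 9.18) and AT5G10040 (3.45 ± 0.29). Of 17 other measured members of a list of such genes all 17 were higher under NPA in sign and 5 passed the test. Their median was 0.60 (camera p 0.00806 with an estimated correlation), or 0.64 over 18 with CML38, which had been seen before. The SE over members, 0.15, is that of their mean. It takes genes as independent, although their estimated correlation was 0.19. The list was chosen because some of its genes were among the largest changes of this same comparison. With correlated members, the signs of the 17 others are not independent of that choice. The camera p values given here were also not adjusted over lists or comparisons. The 17 were higher under NPA in sign, but this test cannot decide whether a list set beforehand would have passed. A day effect shared by both groups cancels in differences within a replicate number, and these had medians of 0.98, 0.57 and 0.27 in numbers 1, 2 and 3 (SE over members 0.16, 0.14 and 0.21), with 15, 15 and 16 of 17 members positive. The median in number 3 thus lies less than 2 SE above 0. Each group has 1 array per replicate number, so putting that number in the model cannot move the median of 0.60 (SE 0.15). Camera in that model gave p 0.00557 with an estimated correlation. A day effect equal in both groups thus cancels by design and not by this check. A day effect that differs between the groups stays open. The order of harvest within a day is not known and stays open.

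Of 45 genes changed in max1 itself against the other 2 mutants, 7 lay within 200 genes of the MAX1 locus, 15.6% against 1.23% of all measured genes (odds ratio 15.4, Fisher exact one-sided p 1.1e-06). These are ATCOAE, AT2G25450, AT2G24960, AT2G25270, AT2G25870, AT2G27330 and AT2G27360, and for them a strain variant linked to the locus had the values it needs. In all 21 of the 45 lay on chromosome 2, between AT2G14110 and AT2G27490, a stretch that holds MAX1, and whether a longer linked segment reaches the others of these was not tested. The 20 on chromosome 1 all lay between AT1G03660 and AT1G12230, and whether they share a strain segment of their own was not tested. Linkage to MAX1 does not reach these 20. For max2 (0 of 7, odds ratio 0, exact p 1.00) and max3 (2 of 30, odds ratio 5.62, exact p 0.0550) it cannot be told apart, since so few genes decide nothing. An effect of MAX1 loss on these genes was not tested apart from it.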

How the results depend on the processing

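All alternatives reported in this part were planned. Of 650 named gene values that passed, 380 did so in every alternative, 270 lost the threshold in at least 1 and 0 reversed. Counts of probe sets kept within 1.5 times their value except as follows, where the cause was not tested unless fewer probe sets or arrays were used. Only probe sets naming 1 gene gave 3085 for decapitation, 2707 for IAA against decapitation, 924 for IAA against intact, 3424 for NPA, 226 for NPA against decapitation, 413, 330 and 182 for max1, max2 and max3, 561 for their mean, 24 for max2 against the others, 49 for max1 against max3, overlaps of 2345, 1909 and 98 (decapitation with NPA, back by IAA, all 3 mutants) and a correlation of 0.165. A change of at least 1 gave 2982, 2433, 927, 2860, 227, 482, 405, 233, 497 and 53 in the same order without max2 against the others, and overlaps of 2248, 1810 and 129. Subtracted array medians gave 11690 for decapitation, 12905 for NPA and 9994 for their overlap. The replicate block gave 2962 (IAA against intact), 1068 (NPA against decapitation), 1418, 1169 and 971 (max1, max2, max3), 2010 (their mean), 144 (max1 against max3) and 423 (all 3 mutants). Fits of only the groups compared gave 900, 0 (limma, 2557 at an unadjusted p below 0.05), 198, 106, 123, 5 (max2 against the others), 17 and 17 for the same results without the mean. Array quality weights gave 256 (NPA against decapitation), 2164, 1152 and 1526 (max1, max2, max3), 2426 (their mean), 280 (max1 against max3) and 611 (all 3). Leaving out 1 array at a time gave 1230 to 1847 (IAA against intact), 270 to 518 (NPA against decapitation), 499 to 639 (max1), 450 to 625 (max2), 217 to 306 (max3), 719 to 1295 (their mean), 25 to 74 (max2 against the others), 136 to 247 (all 3) and a correlation of 0.102 to 0.176, with the arrays that moved each named beside its count in the report. Camera with an estimated correlation kept 7 of 103 list calls. Beside the calls given with their result, the replicate block ended those of ndhH (IAA against decapitation, 0.0518) and of the jasmonate (max2, 0.0633), CLE and RALF (NPA against decapitation, 0.0806), calmodulin-like (max2 against the others, 0.0515) and subtilase (max1 against max3, 0.0531) lists, and it changed no other call reported here. Signal near background limits folds of genes below 3.5.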

Other observations

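The test of the correlation without a shared array and the splits below were set before their results were seen, and the tests of low-oxygen genes in further comparisons were chosen only after the list had been written from results seen. Genes known from low-oxygen responses also moved against intact plants. Of the 17 members not seen before, 11 rose under NPA (median 1.46, camera p 0.0477 with an estimated correlation), 8 in decapitated plants with IAA (median 1.19, camera p 0.00152) and 7 rose and 1 fell after decapitation (median 0.23, camera p 0.345). AT4G27450 rose from 11.39 in intact plants to 12.91 after decapitation and 14.07 under NPA. In max1, max2 and max3 1, 1 and 0 of the 17 were higher. Against decapitated plants IAA raised 5 and lowered 0 of the 17, with 10 positive in sign (median 0.50, camera p 0.134 with an estimated correlation). The rise over decapitated plants was thus not seen under NPA alone. These camera p values were not adjusted over lists or comparisons.

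Log2 differences of decapitation and of the max mutants went together with r 0.129 where the intact arrays are shared. With decapitated plus IAA arrays in place of intact ones r was -0.0105, within -0.0485 to 0.0406 of simulated unchanged groups. Whether the shared arrays are the whole cause cannot be told apart, because that contrast also holds the effect of IAA and the covariance of 0.0478 lay above the highest simulated 0.0308.

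For the other counts, the 10 splits of 6 arrays are too few to reach a share below 0.05. The real split and the highest other called 4349 and 0 for decapitation, 3749 and 0 for IAA against decapitation, 900 and 0 for IAA against intact, 4379 and 0 for NPA, 198 and 0 for max1, 106 and 0 for max2, and 123 and 1 for max3, so that 1 of 10 splits gave as many in each. For the mean of the max mutants the real split called 808 (1 of 100 splits gave as many). The highest other, with the 3 max1 arrays against the rest, called 55. Splits that mix genotypes put the differences between them into the noise. With 1 intact group of 3 arrays they therefore cannot decide whether chance differences between groups gave the count. The other splits that kept every replicate pair apart called 0 in each of the comparisons of 6 arrays.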
